A study of Mus musculus with 2 samples.

How the data were processed

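Cortex of mice at postnatal day 5 was measured by droplet single-cell RNA sequencing in 2 libraries, 1 from wild-type animals (WT) and 1 from animals with a mutation of Katnal2 (Mut). Per the labels' protocols, the tissue was dissociated with trypsin and then with a collagenase, strained, sorted by flow cytometry and loaded on a 10x Genomics Chromium controller. The marker or gate of the sort, the kit chemistry and the part of Katnal2 that is mutated were not given in the sources used here. The series' design text speaks of 3 replicates per sample, but the deposited barcodes of a library carry a single suffix, so cells could not be assigned to animals and each genotype counts as 1 sample.

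The authors deposited raw counts of unique molecular identifiers (UMIs) per gene and barcode. Per the file headers, both matrices were written by Cell Ranger 4. Per the submitters' processing notes, Cell Ranger and STAR were used with the mouse build GRCm38; the annotation release was not given in the sources used here. The matrices hold 32285 genes and every barcode, so no cells had been called by the authors in these files. The other deposited tables hold barcode names and gene identifiers with symbols. The WT library holds 93664707 UMIs over 1957831 barcodes and the Mut library 97891513 over 1974760, and barcodes of at least 1000 UMIs hold 90.6% and 90.7% of them. Gene positions and transcript lengths came from GENCODE annotation of GRCm38, in which 32158 of the 32285 identifiers were found.

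Barcodes with at least 1000 UMIs, at least 500 genes and at most 20% mitochondrial UMIs were taken, 11024 in WT and 10102 in Mut. Doublets were scored per library with Scrublet in scanpy 1.11.5, and the highest-scoring barcodes were removed at the rate expected for this platform, 0.8% per 1000 barcodes: 972 in WT (8.8%) and 816 in Mut (8.1%). The tool's automatic threshold would have removed 390 (3.5%) and 396 (3.9%). This left 10052 and 9286 cells with a median of 6211 and 7322 UMIs, 2625 and 2971 genes and 4.05% and 3.44% mitochondrial UMIs. UMIs in barcodes of 10 to 100 UMIs were taken as RNA free in the suspension.

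Both libraries were clustered together without alignment: log-normalized values of 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1. A cluster's score for a cell type was the mean, over the markers fixed before the data were examined, of the marker's counts per 1000000 UMIs (CPM) relative to the cluster where it is highest. A cluster was named "-like" for the best-scoring type with a score of at least 0.4, a lead of at least 0.06 and at least 3 markers detected in 10% of its cells or more, unless its 10 leading genes held more markers of another type. The markers were fixed in advance, whereas the scoring rule was settled after cluster scores had been seen: a first version ranked leading genes by log difference and left the macrophage cluster unnamed, and the lead was first 0.04. Clusters whose astrocyte and radial glia scores lay within 0.06 of each other form a class called mixed astroglia, also made after the scores were seen. Barcodes with at least 100 Ttr UMIs and at least 3 other choroid plexus markers were set apart by a rule written after the data were seen. An earlier exploratory run used approximate neighbours; the values given come from exact ones.

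For each class with at least 100 cells in both libraries, UMIs were summed per library and expressed as CPM, and the log2 ratio of Mut to WT was taken after adding 5 CPM. There is no replicate of either genotype, so no test was made and no p-value is given. Sums carry exact Poisson 95% intervals, shares carry exact Clopper-Pearson 95% intervals, and ratios carry exact conditional binomial 95% intervals. All of them cover counting error only, not differences between animals, dissections or library preparations, and a difference between these libraries cannot be assigned to genotype. For a share of 0, the limit is that of 3 counts. Gene lists fixed in advance, 10 on the study's subject and 25 others, were summarised by the median log2 ratio of members with at least 30 UMIs in the class. That median is given with its percentile among 10000 random lists of the same size matched on expression in 20 bins, as a description of these 2 libraries. Across classes, the median over classes was used for each gene. Of the members listed, 7 symbols were not found in the gene table used here.

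Genes were named by size alone, by a rule fixed before the data were examined. Across classes it took the 15 highest and 15 lowest median log2 ratios among genes with at least 50 CPM in at least 4 classes and 1 direction in all of them. Per class it took the 5 highest and 5 lowest among genes with at least 50 UMIs and 100 CPM that were not mainly free RNA. Mitochondrial, haemoglobin and sex-linked genes were left out of these ranks. The text prints most but not all of the genes per class. Genes with near-identical copies or many processed pseudogenes (the Rpl, Rps and Hist genes and H2-K1 here) are uncertain, since the counting could assign their reads elsewhere.

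Cells were also split by sex from their own RNA, after the data had been seen: a cell with Xist and no Y-linked UMI was called female, and one with Y-linked UMIs and no Xist male. Alternatives set before the data were seen changed the UMI minimum (500 or 2000), the mitochondrial maximum (10%), doublet removal, the Leiden resolution (0.5 or 2), the centring of each library before clustering, the scaling (edgeR 4.0.16 TMM factors), the pseudocount (1 CPM), the depth (each cell thinned to 1000 UMIs), the minimum for measured genes (10 or 100 UMIs) and the treatment of free RNA (subtracted). Thinning was a single random draw, so its values for genes in small classes rest on few UMIs. In the alternatives that recluster the cells, a cluster took the class that most of its cells held in the main clustering. Naming clusters afresh had been tried first and had moved many astroglial cells, so the shares vary less than fresh names would make them. The ratio intervals and list percentiles were tested on simulated data with known changes. Intervals held the true ratio for 95.2% and 96.2% of 2000 genes drawn per class, from 13701 simulated astrocyte genes and 9712 simulated radial glia genes. Of 100 unchanged lists, 1 and 4 lay outside the middle 95% of random lists, and a changed list lay at the 100th percentile in both. Counts were simulated with counting error alone, and the unchanged lists were random draws of genes. These checks therefore test the computation and do not show how often lists of genes that vary together lie outside.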

Results

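Single-cell transcriptomes of postnatal day 5 mouse cortex were compared between 1 wild-type library (WT) and 1 library from Katnal2 mutant animals (Mut). Katnal2 encodes a protein related to the microtubule-severing ATPase katanin, and the study's title links its mutation to enlarged brain ventricles, vesicle trafficking and the polarity of ependymal cells. After filtering, the WT library held 10052 cells with a median of 6211 UMIs and the Mut library 9286 cells with a median of 7322. Each genotype has 1 library, so the values below have no replicate check. Their intervals cover counting error only, and the direction of a difference is given for these libraries alone.

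Both libraries held cells of both sexes. In WT, 3488 cells had Xist without any Y-linked UMI and 3916 the reverse, and in Mut these were 4884 and 2598. Female cells made up 47.1% of the assigned cells in WT (95% interval 46.0 to 48.3) and 65.3% in Mut. Cells with both kinds of UMI were 1.51% and 2.27% of all cells, against 14.7% and 16.6% if the signals were independent, so each library pools animals of both sexes. Values in female and male cells are given beside some results, and many others part between them as well.

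Katnal2 (ENSMUSG00000025420, chromosome 18, 76977148 to 77047308, minus strand, GRCm38) had its highest level in ependymal cell-like cells. It had no UMI in oligodendrocyte-like, microglia-like, monocyte-like and border-associated macrophage-like cells of either library. In ependymal cell-like cells it stood at 85.0 CPM in WT (95% interval 40.8 to 156) and 106 in Mut (67.1 to 159), from 10 and 23 UMIs. Radial glia-like cells had 14.8 CPM in WT and 10.9 in Mut, with a ratio of 0.735 and an interval of 0.394 to 1.34. Mixed astroglia-like cells had 7.36 and 9.46 CPM, and oligodendrocyte precursor-like cells 5.16 and 5.67. For microglia-like cells the count of 0 allows at most 1.45 CPM in WT and 1.63 in Mut. These limits were 3.1 and 3.35 CPM for oligodendrocyte-like and 5.82 and 2.15 for border-associated macrophage-like cells. For monocyte-like cells they were 47.6 and 26.6 CPM, too high to show that Katnal2 is absent there. Over all kept cells the level was 4.03 CPM in WT (290 UMIs) and 4.94 in Mut (378 UMIs), a ratio of 1.23 with an interval of 1.05 to 1.43. In astrocyte-like cells the ratio was 1.56 (1.11 to 2.22), at levels of 2.08 and 3.24 CPM that lie near the free RNA levels of 2.11 and 3.87 CPM. The mutated part of the gene was not stated, so the RNA level does not check the genotype labels.

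**Figure D1:**
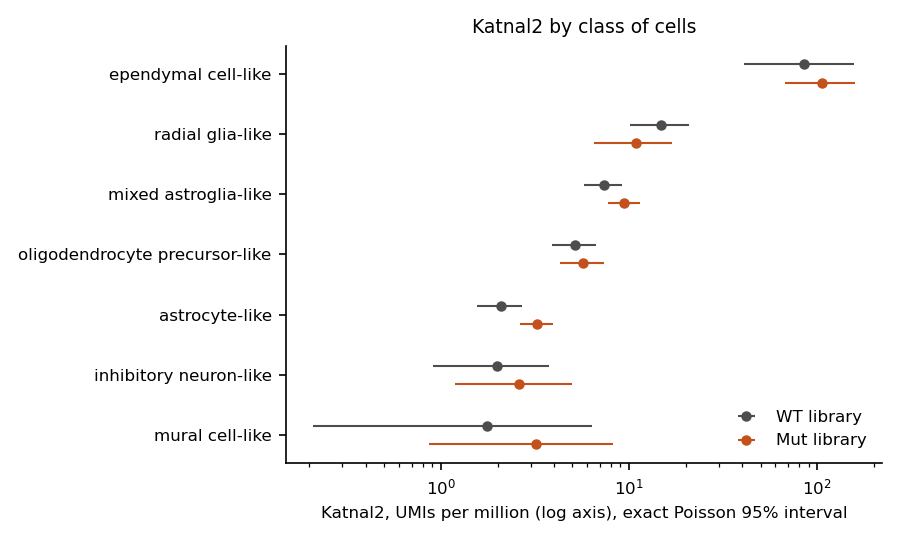
Katnal2 in CPM on a log axis, by class of cells with at least 3 Katnal2 UMIs, in the WT and Mut libraries; points are class sums and bars exact Poisson 95% intervals. Ependymal cell-like cells hold 85.0 and 106 CPM, above every other class in both libraries.

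The cells fell into glial, neuronal, vascular and immune classes, but no cluster of the main clustering was named for excitatory neurons. A cluster with Neurod6, Neurod2 and Tbr1 among its leading genes, of 44 WT and 48 Mut cells, stayed unnamed. Among named classes whose ratio intervals left out equal shares, the largest ratios between the libraries lay outside the neural lineage. Fibroblast-like cells were 0.478% of WT cells (48 cells) and 1.47% of Mut cells (136), a ratio of 3.07 with an interval of 2.19 to 4.36. Border-associated macrophage-like cells, the macrophages of the meninges and perivascular spaces, were 0.915% and 2.37%, with a ratio of 2.59 (2.02 to 3.34). Endothelial cell-like cells were 2.57% and 3.88%, with a ratio of 1.51 (1.28 to 1.78). On the other side, inhibitory neuron-like cells were 12.5% of WT and 8.92% of Mut cells (ratio 0.711, 0.651 to 0.777), radial glia-like cells 4.94% and 4.00% (0.808, 0.704 to 0.926) and microglia-like cells 3.92% and 3.26% (0.832, 0.714 to 0.969). Tissue dissection, enzyme treatment and the sort can all set these shares.

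Astrocyte-like cells made up 31.0% of WT and 33.6% of Mut cells (ratio 1.09), a share that depends on the naming of clusters. Oligodendrocyte precursor-like cells were 18.0% and 17.8% (ratio 0.987, 0.923 to 1.06), and the ratio for oligodendrocyte-like cells was 0.934 (0.720 to 1.21). Mixed astroglia-like cells, mostly dividing cells between astrocyte and radial glia, stood at 8.57% and 8.90%. Mural cell-like, Cajal-Retzius cell-like and monocyte-like cells had ratios of 1.18, 1.06 and 1.72, with intervals that include 1. Ependymal cell-like cells, the multiciliated cells that line the ventricles, numbered 9 in WT and 14 in Mut, a ratio of 1.68 that its interval of 0.679 to 4.41 does not set apart from 1. Clusters left unnamed by the marker rule held 12.5% of WT and 10.5% of Mut cells.

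The Mut to WT ratios of the meningeal classes were larger in male than in female cells, and their shares differed between the sexes within WT too. Fibroblast-like cells were 1.03% of female and 0.204% of male WT cells (36 and 8 cells), against 1.29% and 1.85% in Mut. Border-associated macrophage-like cells were 1.72% and 0.587% in WT (60 and 23 cells), against 2.33% and 2.81% in Mut. The large male ratios thus rest on few male WT cells. The fibroblast-like ratio was 1.25 in female cells (0.817 to 1.94) and 9.04 in male cells (4.24 to 22.1), and the border-associated macrophage-like ratio was 1.36 (0.984 to 1.89) and 4.78 (2.96 to 8.01). The inhibitory neuron-like ratio was 0.672 in female cells (0.573 to 0.789) and 0.951 in male cells (0.816 to 1.11). Endothelial cell-like cells had similar ratios in both, 1.34 and 1.36. Within classes, a cluster of astrocyte-like cells led by Six3 and Crym had a ratio of 0.622 (0.518 to 0.744), and a cluster of inhibitory neuron-like cells led by Sst, Npy, Six3 and Foxp2 had 0.467 (0.352 to 0.615). A cluster of astrocyte-like cells led by Serpinf1 and Gfap, with MHC class II genes among its leading genes, had 1.44 (1.27 to 1.64). Of the fibroblast-like clusters, 1 held 29 cells of Mut and 0 of WT and may be specific to that library rather than to a cell type; the other held 48 WT and 107 Mut cells.

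**Figure D2:**
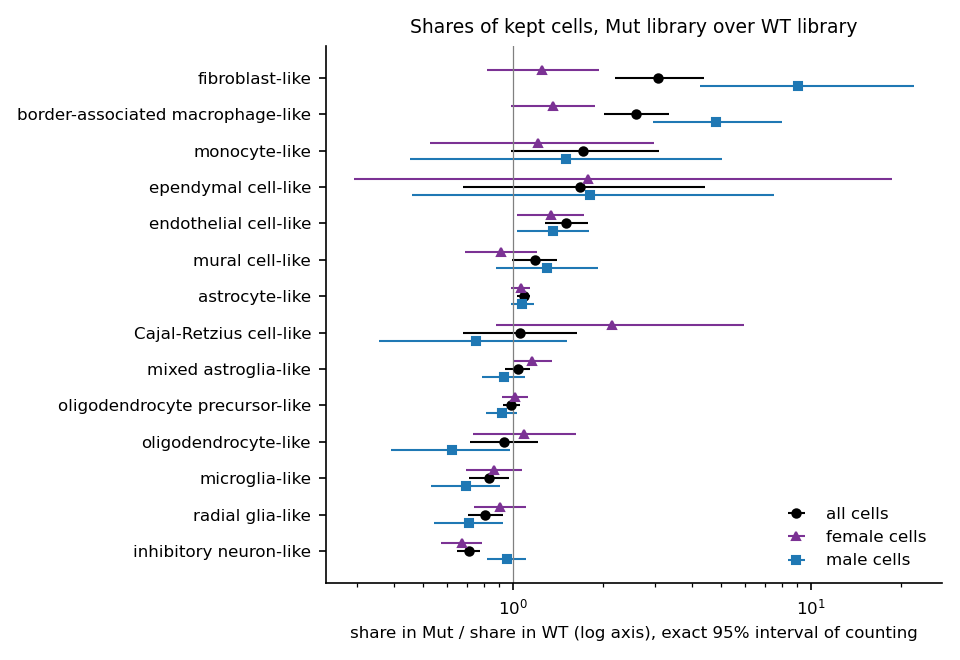
Ratio of the share of kept cells in the Mut library to that in the WT library, by class, on a log axis; bars are exact 95% intervals of counting, for all cells and for female and male cells alone. Fibroblast-like and border-associated macrophage-like cells lie at 3.07 and 2.59 for all cells, and at 9.04 and 4.78 in male cells.

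A small set of housekeeping genes differed between the libraries in the same direction in every class where they had enough counts, 4 to 9 classes for each gene. Lowest in Mut was Rpl29, a protein of the large ribosomal subunit, with a median log2 ratio over 9 classes of -1.30. Tomm22, a receptor of the mitochondrial outer membrane import complex, followed at -1.02, Lars2, the mitochondrial leucyl-tRNA synthetase, at -1.002, the linker histone gene Hist1h1e at -0.77 and Smdt1, a regulator of the mitochondrial calcium uniporter, at -0.49. Hist1h4d (-0.50), Rps2 (-0.44), Rps18 (-0.40), Hist3h2ba (-0.38), Tsr3 (-0.35), Txnl4a (-0.33), Snapc1 (-0.32), Dtnbp1 (-0.31) and Cbr3 (-0.28) were lower as well. Snapc1 lost its difference with cells thinned to 1000 UMIs (-0.0030) and Dtnbp1 in female cells (-0.058). In astrocyte-like cells Tomm22 stood at 128 CPM in WT and 59.6 in Mut, a ratio of 0.464 with an interval of 0.438 to 0.492. Lars2 had 28155 of 71954402 UMIs in the kept WT cells and 14053 of 76590111 in the kept Mut cells. Its level was higher in free RNA, at 1446 CPM in WT and 722 in Mut.

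Higher in Mut were several small nuclear-encoded proteins of the mitochondrion and ribosome. Atp5md (median log2 ratio 0.61) and Atp5mpl (0.52) encode small subunits of ATP synthase, Ndufa3 (0.45) a subunit of complex I, Pet100 (0.47) and Cox17 (0.39) assembly factors of complex IV, and Romo1 (0.42) an inner membrane protein. Rpl39 (0.44), Rpl38 (0.40) and Rps27 (0.39) encode ribosomal proteins. The ribosomal genes among them do not stand for their group: of the 38 listed ribosomal protein genes 23 were lower in Mut across classes (median -0.062, percentile 0.04; 7.13 in female cells, inside the random range), as were Rpl29, Rps18 and Smdt1 above. Lamtor3 (0.73), Hist1h2ap (0.52), the MHC class I gene H2-K1 (0.48), the metallothionein gene Mt3 (0.42), Acat2 (0.41) and the RNA gene Snhg8 (0.39) were higher as well. In astrocyte-like cells Atp5md stood at 229 CPM in WT and 361 in Mut (ratio 1.57, 1.53 to 1.63).

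For most of these 30 genes female and male cells gave similar values, and for several they did not. Tomm22 had median log2 ratios of -1.04 in female and -1.05 in male cells, and Atp5md 0.61 and 0.51. Rpl29 had -0.69 in female and -3.97 in male cells. Within the Mut library its level in female cells lay 3.36 log2 units above that in male cells, against 0.05 within WT. H2-K1 had 1.48 in female and -0.08 in male cells, Lamtor3 1.33 and -0.11, Hist1h4d -1.25 and 0.09, Rps18 -0.82 and 0.02, Rps2 -0.72 and -0.17, and Acat2 0.69 and 0.09.

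**Figure D3:**
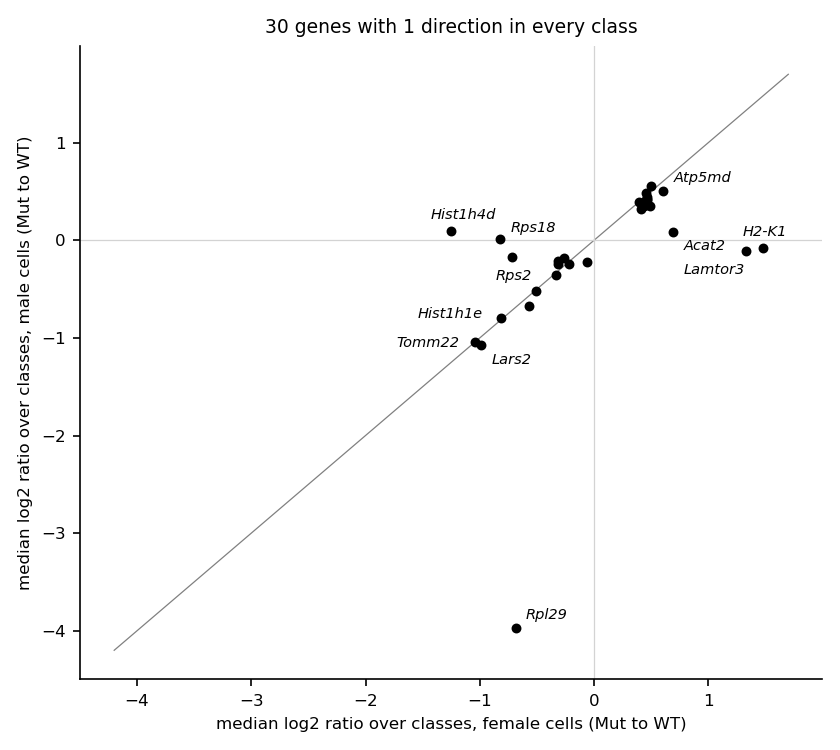
Median log2 ratio over classes (Mut to WT) in female cells (horizontal axis) and male cells (vertical axis) for the 30 genes named across classes; each point is a gene and the diagonal marks equal values. Tomm22 lies on the diagonal at -1.04 and -1.05, whereas Rpl29 lies at -0.69 and -3.97 and H2-K1 at 1.48 and -0.08.

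The lists on cilia, polarity and vesicle trafficking, the subjects in the study's title, showed little net difference in radial glia-like cells, the class related to ependymal cells that was deep enough to compare. Of 26 measured motile cilium genes 13 were higher in each library, with a median log2 ratio of 0.01 at the 29.6th percentile of random lists. Cfap45 (0.78) and Dynlrb2 (0.54) were among the highest. Basal body and intraflagellar transport genes split 22 to 21 (median 0.00, percentile 19.4), with Ift172 at 0.99 and Bbs1 at -0.49. Cell polarity genes split 14 to 11 (percentile 42.5; Pard6g 0.25, Scrib -0.21), and adherens and tight junction genes 7 to 8 (percentile 21.8; Ctnnd1 -0.24). The motile cilium list is sensitive to which cells the class holds. It lay at the 0.01st percentile with a UMI minimum of 500, at the 0th with a mitochondrial maximum of 10% and at the 0.28th without doublet removal. It lay at the 100th at Leiden resolution 0.5 and with each library centred before clustering, as did the basal body and intraflagellar transport list. No direction can be given for either list in this class. The radial glia-like class held 8 WT and 10 Mut cells with at least 4 of 9 ciliary markers.

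Trafficking lists lay inside the random range in radial glia-like cells as well, clathrin endocytosis least firmly. Endosome and retromer genes split 19 to 17 (percentile 27.8), exocyst, Golgi and secretory vesicle genes 23 to 16 (72.4), SNARE and membrane fusion genes 16 to 16 (13.2) and microtubule and katanin genes 23 to 14 (54.8). Examples were Rab4a, a GTPase of endosomal recycling (0.59), Stx12 (0.47), Katna1 (0.49) and Map1b (-0.48). Clathrin endocytosis genes were higher in Mut for 19 of 23 members (median 0.12, percentile 95.9), with Synj1 at 0.71 and Itsn1 at 0.57, and lay outside the range with no doublets removed (99.2) and with cells thinned (98.1). Planar cell polarity genes, which orient cells within a sheet, were higher in Mut for 14 of 17 members, with a median of 0.17 at the 98.1st percentile (Dvl3 0.58, Fzd6 0.46, Dchs1 -0.38). That position does not hold: it was lost in 10 alternatives set before the data were seen, down to 65.1 with cells thinned, and in female cells (68.0) and male cells (48.0) taken alone.

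Across the 9 classes the same 10 lists lay inside the middle 95% of random lists with the processing used here, but 4 of them did not under some alternatives: clathrin endocytosis (up to 99.5 with cells thinned), planar cell polarity (up to 98.9 with TMM scaling), basal body and intraflagellar transport (down to 0.14 with TMM scaling) and motile cilium (2.10 with at least 10 UMIs per gene). Planar cell polarity came nearest on the Mut side (16 of 19 members higher, median 0.10, percentile 96.9; Dvl1 0.25, Vangl1 0.22), and basal body and intraflagellar transport on the WT side (22 of 43 higher in Mut, median 0.02 against 0.05 for random lists, percentile 4.03). Clathrin endocytosis lay at 90.8, microtubule and katanin at 83.4, adherens and tight junction at 69.6, exocyst, Golgi and secretory vesicle at 56.0, endosome and retromer at 44.8, SNARE and membrane fusion at 32.6, motile cilium at 23.4 and cell polarity at 20.5. Among single trafficking genes Rab4a stood out, with a median log2 ratio of 0.55 and a range over classes of 0.31 to 0.76. In the 9 and 14 ependymal cell-like cells, motile cilium genes took 2.31% of UMIs in WT and 2.40% in Mut, a ratio of 1.04 with an interval of 0.992 to 1.09.

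**Figure D4:**
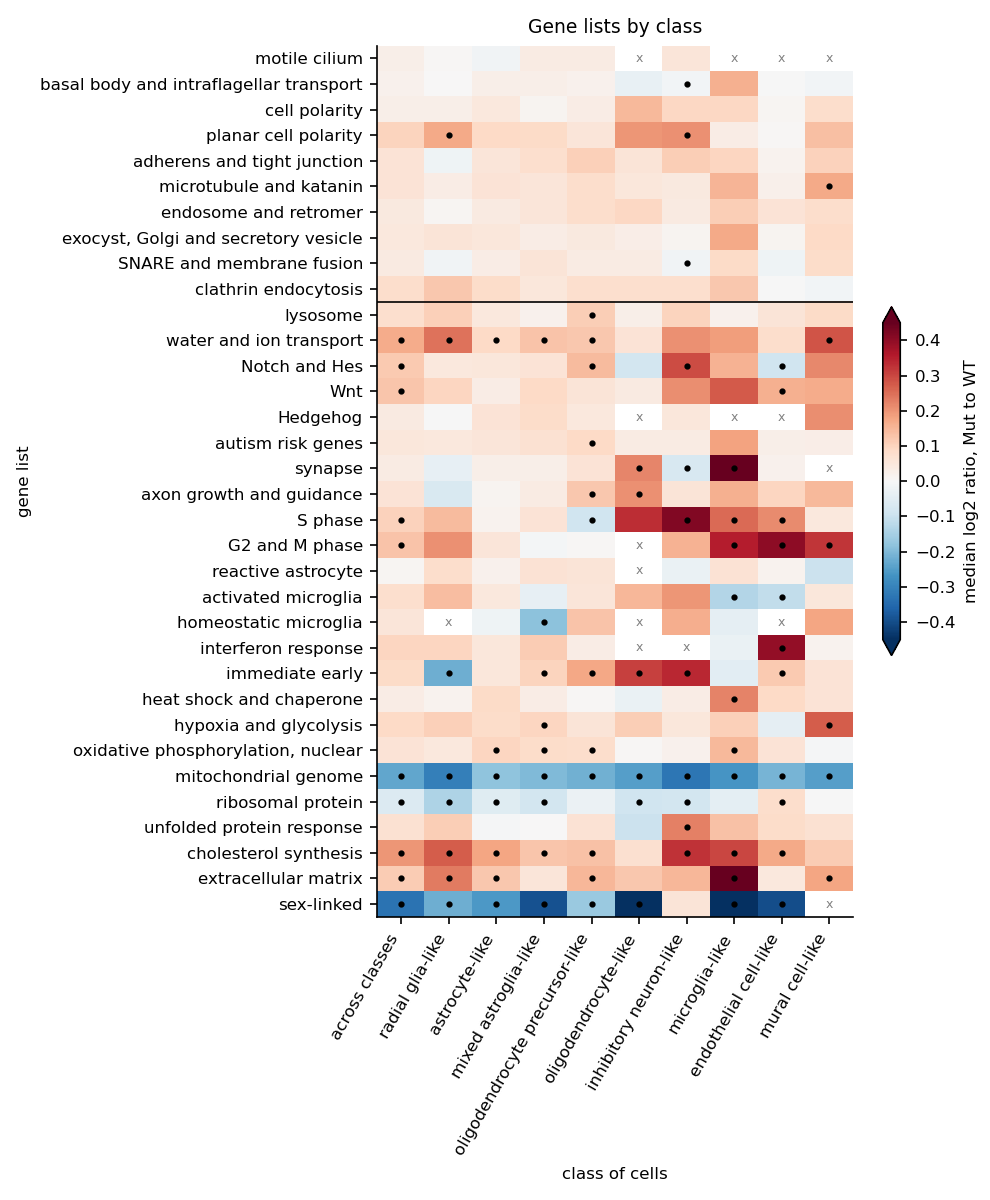
Median log2 ratio (Mut to WT) of each gene list in each class and across classes; the colour scale ends at 0.45 in both directions, dots mark medians outside the middle 95% of random lists, crosses mark lists with under 5 measured genes, and the line parts the 10 lists on the study's subject from the others. The mitochondrial genome is on the WT side in every column, with a median of -0.23 across classes.

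Transcripts of the mitochondrial genome were lower in Mut in each of the 9 classes, the largest median across classes after that of the sex-linked list (-0.33). Across classes 12 of 13 members were lower, with a median log2 ratio of -0.23 at the 0th percentile; mt-Atp6 had -0.44 and mt-Co2 -0.38. In radial glia-like cells the median was -0.31, and in inhibitory neuron-like cells, where all 13 were lower, -0.33. Female and male cells gave -0.24 and -0.27 across classes. Nuclear genes of oxidative phosphorylation did not share this: 22 of 31 were higher in Mut, with a median of 0.06 (percentile 87.5), and they lay outside the random range on the Mut side in astrocyte-like (99.7), mixed astroglia-like (99.6), oligodendrocyte precursor-like (98.8) and microglia-like cells (97.9). Of these, astrocyte-like and oligodendrocyte precursor-like cells lost the position in male cells (93.3 and 95.6), microglia-like cells in female and male cells (96.9 and 89.0), and mixed astroglia-like cells with thinning (69.3).

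Sterol and transport genes were higher in Mut. Cholesterol synthesis genes were higher for 19 of 20 members across classes (median 0.20, 100th percentile), among them Lss (0.39) and Fdft1 (0.28). In male cells alone that median was 0.05 (percentile 57.5). In radial glia-like cells 19 of 20 were higher as well, with a median of 0.27 (Fdps 0.47), and there both female (0.40) and male cells (0.20) lay outside the random range. Water and ion transport genes, which include the transporters of fluid secretion, were higher for 16 of 16 members across classes (median 0.17, 100th percentile; 96.95 in female cells, inside the random range), with the bicarbonate transporter gene Slc4a4 at 0.29 and the potassium channel gene Kcnj10 at 0.22. In radial glia-like cells 13 of 15 were higher (median 0.25, percentile 99.9), led by Slc12a2, the sodium-potassium-chloride cotransporter gene, at 0.55. With cells thinned to 1000 UMIs that list lay at the 85.2nd percentile. Extracellular matrix genes (15 of 15 higher, percentile 98.97), Wnt (16 of 19, 99.6), Notch and Hes (17 of 19, 99.5), G2 and M phase (25 of 25, 99.95) and S phase genes (20 of 23, 98.6) also lay on the Mut side across classes, with medians of 0.12, 0.12, 0.12, 0.13 and 0.10. Not all of these hold: G2 and M phase genes lay at 76.1 with no doublets removed and 75.3 with cells thinned, S phase genes at 33.3 in male cells, and extracellular matrix genes at 86.7 in female cells. Notch and Hes genes (78.1 and 89.9) and Wnt genes (90.6 and 94.8) were inside the random range in female and in male cells. Ribosomal protein genes were lower in radial glia-like cells for 31 of 38 members (median -0.14, 0th percentile; Rpl3 -0.38, Rpl13 -0.36).

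Of the 290 list and class pairs computed, 80 lay outside the middle 95% of random lists, and 28 did so on the same side in all, female and male cells. Among the 28, inhibitory neuron-like cells had higher S phase genes in Mut (23 of 23, median 0.42; Mcm2 0.88), immediate early genes (16 of 17, 0.34; Egr1 1.02, Fos 0.85) and cholesterol synthesis genes (17 of 20, 0.33). The cluster led by Sst and Npy held 176 of the 1260 WT cells of this class and 76 of its 828 Mut cells. Synapse genes there had a median of -0.07 (0th percentile), with -0.34 in female and 0.11 in male cells. How far the mix of clusters sets these differences was not tested. Vascular and immune cells had higher G2 and M phase genes: 25 of 25 in endothelial cell-like cells (median 0.40; Top2a 0.72), 25 of 25 in mural cell-like cells (0.32; Prc1 0.57) and 24 of 25 in microglia-like cells (0.36; Mki67 0.56). The endothelial value moved inside the random range, to 8.44 on its WT side with no doublets removed and to 65.4 with cells thinned. The microglial value lay at 94.5 with no doublets removed. Endothelial cell-like cells also had higher interferon response genes (12 of 15, median 0.40; Irf7 0.75). Oligodendrocyte precursor-like cells had lower S phase genes (18 of 23, -0.09) and higher autism risk genes (31 of 39, 0.09, percentile 98.8; Chd8 0.33, Nlgn3 0.27), a position lost at a UMI minimum of 500 (97.1) and with cells thinned (94.0).

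Other leading genes were named class by class, which does not make them specific to the class: over classes Snhg6 had a median log2 ratio of 0.37, Sept3 0.36, Nr2f1 0.33 and Pax6 0.28. Astrocyte-like cells had higher Sept3 (log2 ratio 0.66), Serpinf1 (0.57; 0.28 in female cells) and Klf4 (0.56) in Mut. Serpinf1 leads the astrocyte-like cluster that held more Mut cells. Sept3 was also higher in mixed astroglia-like (0.76) and radial glia-like cells (0.70). Radial glia-like cells had higher Nr2f1 (0.67), a transcription factor of cortical patterning, and lower Fosb (-0.72). Oligodendrocyte-like cells had higher Lpar1 (1.55; 2.24 in female and 0.91 in male cells, 2.56 thinned), with 42.0 CPM in WT and 132 in Mut, Ephb1 (1.08; 1.81 in female cells, 0.34 thinned) and Parvb (0.83), and lower Gadd45g (-0.80; -0.13 in female and -1.43 in male cells). Oligodendrocyte precursor-like cells had lower Tmem179 (-0.86) and Rasl11a (-0.63). Inhibitory neuron-like cells had higher Pax6 (0.60) and Snhg6 (0.65). They had lower Npy (-0.82), at 584 CPM in WT and 329 in Mut, and Pcp4 (-0.54; -1.51 in female and -0.0090 in male cells). Both are leading genes of the Six3 and Foxp2 cluster that took fewer Mut cells, and Npy stood at 1.08 with a UMI minimum of 500 and at -3.61 in female against 0.30 in male cells. Pcp4 stood at 0.16 with a UMI minimum of 500 and at 0.027 with no doublets removed.

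Microglia-like cells had lower Trem2 (-0.56), at 1185 CPM in WT and 804 in Mut (ratio 0.679, 0.640 to 0.719), lower Ccl7 (-0.86) and Egr3 (-0.59), and higher Lgals1 (0.66) and Cenpf (0.62; 0.17 with no doublets removed). Scaling by TMM shifts all microglia-like ratios by -0.12, which leaves these directions as they are. In endothelial cell-like cells the elastin gene Eln stood at 270 CPM in WT and 3.31 in Mut (log2 ratio -5.05) and the matrix gene Mgp had -3.10. With a mitochondrial maximum of 10% they had -3.72 and -1.94. The other extremes were -5.98 for Eln with a pseudocount of 1 CPM and -4.17 for Mgp with no doublets removed. The WT signal of both genes lay in female cells, with Eln at 829 CPM in female and 0.48 in male cells of WT, and Mgp at 358 and 8.57. Extracellular matrix genes as a list parted there too, with a median of -0.17 in female cells (percentile 0.53) and 0.19 in male cells (99.1), and lay at 67.8 in all cells. Endothelial cell-like cells also had lower Aldh2 (-0.86) and higher Nr4a1 (0.61). Mural cell-like cells had higher Dlk1 (0.88) and Car4 (0.74), and lower Col1a1 (-3.34; -1.32 in female and -3.54 in male cells), from 126 UMIs in WT and 8 in Mut.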

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

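In this part the tests on blocks of chromosome, on the Katnal2 region and on transcript length were set before their results were seen, although the Katnal2 test was matched on expression only after a first unmatched result, and the other 5 tests and the split into female and male cells were chosen afterwards.

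Several genes had opposite signs in female and male cells, and these differences between female and male cells were not tested. Among genes that differed across classes, the median log2 ratio was 1.33 in female and -0.11 in male cells for Lamtor3, a scaffold of lysosomal signalling, and 1.48 and -0.081 for the MHC class I gene H2-K1. The histone gene Hist1h4d had -1.25 and 0.093, and the ribosomal protein gene Rps18 had -0.82 and 0.018. In endothelial cell-like cells the elastin gene Eln had -6.54 and 0.30 and the matrix gene Mgp -4.69 and 0.24. The male values of Eln rest on levels of 0.48 CPM in WT and 1.73 in Mut, too low to give it a sign there, whereas female WT cells had 829 CPM. In inhibitory neuron-like cells the neuropeptide gene Npy had -3.61 and 0.30. In mural cell-like cells the histone gene Hist1h2ap was higher in Mut in all cells (0.69) and had -0.046 in male cells. Ttr, a gene of choroid plexus, stood at 477 CPM in the Mut library's free RNA, against 20.04 CPM in WT.

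Genes such as Rpl29, Tomm22 and Lars2 differed between the libraries in every class where they had enough counts. RNA free in the suspension made up an estimated 0.61% to 3.70% of the UMIs of a class. Subtracting it kept a median of 1.005 of the log2 ratio of the 30 genes and moved no result. Subtracting so small a share could hardly move a ratio, so the 1.005 kept does not decide whether free RNA is a source of the 30 ratios. What can be said is that the estimated share was small in every class. Different forms of a gene among the pooled animals stay open for 5 of the 30 genes, Lamtor3, H2-K1, Rpl29, Hist1h4d and Rps18, which differ by at least 0.5 (log2) between female and male cells in at least 1 library, values that were seen before the explanation was considered. Blocks of chromosome from another strain stay open too. Of 26 genes other than histone genes, 6 lie within 5 Mb of another, against 3 in the median random list (percentile 86.5). They are H2-K1 with Rps18 and Rps2 with Tsr3 on chromosome 17, and Tomm22 with Smdt1 on chromosome 15. A block around Katnal2 stays open as well, where 17 genes within 10 Mb, Txnl4a among them, lie at the 94.7th percentile. The explanations left open cannot be told apart from an effect of the mutation, because each genotype has 1 library.

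Of the genes highest in Mut across classes, 9 are short nuclear genes of the mitochondrion and ribosome, among them Atp5md, Cox17 and Rpl39, while transcripts of the mitochondrial genome were lower. They were picked for being the highest. Of 38 ribosomal protein genes 23 were lower, as were the short genes Smdt1, Rps18 and Rpl29, whereas 22 of 31 nuclear genes of oxidative phosphorylation were higher. Transcript length does not account for all of this. Of 20 length bins of measured genes, the shortest had a median log2 ratio of 0.066 and the longest 0.061. The 9 genes kept 0.85 of their median log2 ratio against genes of like length (0.44 and 0.38). Having been picked as the highest, they would lie above those genes in any case, so that share alone decides little. Damaged cells stay open for the mitochondrial part: it kept 1.018 of its size at a mitochondrial maximum of 10%, but that maximum leaves 10797 of 11024 WT and 9978 of 10102 Mut barcodes in place, so it decides nothing. A batch difference between the libraries was not tested, and with 1 library per genotype it cannot be told apart from the mutation.

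Fibroblast-like and border-associated macrophage-like shares were higher in Mut. More meninges and choroid plexus carried along with the Mut cortex could produce this, and stays open: Ttr in free RNA was 23.8 times as high in Mut as in WT, a value seen before it was used as a test. An effect of the mutation stays open. In 2 of 2 classes the intervals of female and male cells do not overlap, but they leave out differences between animals and so do not bear on it.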

How the results depend on the processing

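The alternatives restricted to female or male cells were chosen after the data had been seen, and the rule that calls a list reversed was corrected after its values had been seen, since it had passed over lists that moved outside the random range on the opposite side. No paired analysis was possible because each genotype has 1 library, and for the same reason no result has a test. Depth limits the small classes: ependymal cell-like cells number 9 and 14, and every interval covers counting alone. The cause was not tested for any value below, except where it is stated.

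Katnal2 over all cells kept its direction and stayed within its interval in all 8 alternatives, 1 of which subtracted free RNA at the largest share of any class. Shares stayed within their intervals in 109 of 121 alternative values. In female cells the ratio moved to 1.36 for border-associated macrophage-like, 1.25 for fibroblast-like, 2.14 for Cajal-Retzius cell-like, 1.16 for mixed astroglia-like and 0.910 for mural cell-like cells. In male cells it moved to 4.78 for border-associated macrophage-like, 9.04 for fibroblast-like, 0.951 for inhibitory neuron-like, 0.696 for microglia-like, 0.930 for mixed astroglia-like, 0.624 for oligodendrocyte-like and 0.916 for oligodendrocyte precursor-like cells. Naming is fragile for astroglia: at Leiden resolution 0.5 and with each library centred before clustering, the cluster named ependymal held 508 and 382, and 499 and 381 cells. With clusters named afresh, the radial glia-like ratio ranged from 0.779 to 0.983, and the astrocyte-like share of WT was 13.6% and 15.2% with UMI minimums of 500 and 2000 and 17.6% at resolution 2, each below that of oligodendrocyte precursor-like cells (18.6%, 18.5% and 18.1%).

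Lists on the study's subject are given as percentiles. A list called reversed passed to the other side of the middle of the random lists, inside or outside the random range. In radial glia-like cells motile cilium genes lay at 0.01 with a UMI minimum of 500, 0.00 with a mitochondrial maximum of 10%, 0.28 with no doublets removed, and reversed to 100 at Leiden resolution 0.5 and to 100 with each library centred. Basal body and intraflagellar transport genes there lay at 2.32 with a mitochondrial maximum of 10% and reversed to 100 and 100 in the same 2 clusterings, where ependymal cells fall into the radial glia cluster and so have no value of their own. Planar cell polarity genes there lay at 94.9 and 95.1 with UMI minimums of 500 and 2000, 91.4 with a mitochondrial maximum of 10%, 82.0 with no doublets removed, 88.2 and 97.46 at Leiden resolutions 0.5 and 2, 88.0 centred, 65.1 with cells thinned, 94.5 and 96.9 with at least 10 and 100 UMIs per gene, 68.0 in female cells, and reversed to 48.0 in male cells. Clathrin endocytosis genes there lay at 99.2 with no doublets removed and 98.1 thinned. Across classes clathrin endocytosis genes lay at 98.1, 99.4, 98.5, 99.01 and 99.5 with UMI minimums of 500 and 2000, the mitochondrial maximum, no doublets removed and thinning. Basal body genes across classes lay at 2.13 with a UMI minimum of 2000, 1.64 with the mitochondrial maximum, 0.78 at resolution 2, 0.14 with TMM scaling, 0.92 with at least 100 UMIs per gene and 2.48 in female cells. Planar cell polarity genes across classes lay at 97.6 at resolution 0.5 and 98.9 with TMM scaling, and motile cilium genes at 2.10 with at least 10 UMIs per gene.

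Of 447 alternative values of the other lists 426 stayed on their side, 16 moved inside the random range and 5 reversed. G2 and M phase genes moved inside across classes at 76.1 with no doublets removed and 75.3 thinned, in microglia-like cells at 94.5 with no doublets removed and in endothelial cell-like cells at 65.4 thinned. Autism risk genes in oligodendrocyte precursor-like cells moved to 97.1 with a UMI minimum of 500 and 94.0 thinned. Immediate early genes moved to 69.2 in endothelial cell-like cells with the mitochondrial maximum, and in mixed astroglia-like cells to 96.1, 97.3, 93.05, 97.4 and 82.1 with a UMI minimum of 2000, the mitochondrial maximum, resolutions 0.5 and 2, and thinning. Thinning also moved water and ion transport genes to 85.2 in radial glia-like and 91.6 in mixed astroglia-like cells, nuclear oxidative phosphorylation genes in mixed astroglia-like cells to 69.3 and unfolded protein response genes in inhibitory neuron-like cells to 91.9. Those that reversed were in endothelial cell-like cells: the activated microglia list to 52.2 with a UMI minimum of 2000, 50.1 with no doublets removed and 65.5 with at least 10 UMIs per gene, and S phase and G2 and M phase genes to 16.2 and 8.44 with no doublets removed. Of the values of genes over classes 278 stayed the same, 18 moved and 4 reversed, and of those of genes in a class 733, 156 and 11, with 41 of the 156 under thinning. Npy in inhibitory neuron-like cells reversed to 1.08 with a UMI minimum of 500, 0.37 with the mitochondrial maximum, 0.65 with no doublets removed and 0.30 in male cells, and Pcp4 to 0.16 with a UMI minimum of 500 and 0.027 with no doublets removed. Ube2c in endothelial cell-like cells reversed to -0.27 with no doublets removed, and Tomm22 in oligodendrocyte-like cells to 0.59 with cells thinned. In male cells Lamtor3 reversed to -0.11, H2-K1 to -0.081, Hist1h4d to 0.093, Rps18 to 0.018, Eln and Mgp in endothelial cell-like cells to 0.30 and 0.24, and Hist1h2ap in mural cell-like cells to -0.046.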

Other observations

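No test in this part was chosen in advance: the Ttr and ciliary marker counts below were made after the cells had been seen, and none is a test of an explanation.

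Cells with a profile of choroid plexus, the epithelium that secretes cerebrospinal fluid, were found in the Mut library alone by a Ttr rule set after the data had been seen, although Ttr RNA was present in both libraries. The Mut library held 9 cells with a choroid plexus profile, with 55941 Ttr UMIs, and the WT library 0, which allows at most 0.0298% of its cells. With a UMI minimum of 2000 the rule found 1 such cell in Mut and 0 in WT, and with no doublets removed 11 and 0. The 9 cells had a median of 16807 UMIs, and doublets were scored afresh at each UMI minimum. The higher minimum alone therefore does not account for the drop. Ttr was also counted in 946 of 9277 other Mut cells (10.2%) and in 26 WT cells (0.26%). Cells with at least 4 of 9 ciliary markers numbered 17 in WT and 30 in Mut (0.169% and 0.323%, ratio 1.91, 1.02 to 3.69), of which 0 and 6 had a choroid plexus profile.

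In ependymal cell-like cells, water and ion transport genes took 0.113% of UMIs in WT and 0.155% in Mut (ratio 1.37, 1.12 to 1.68). Clathrin endocytosis genes had a ratio of 1.23 (1.02 to 1.49), microtubule and katanin genes 1.10 (1.03 to 1.17) and Wnt genes 0.735 (0.585 to 0.926). Planar cell polarity genes had 1.001 (0.807 to 1.25). These are 9 and 14 cells, and the markers of the class themselves had a ratio of 1.16.

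Summed over all kept cells, haemoglobin transcripts were higher in the Mut library, with Hba-a1 at 137 CPM in WT and 339 in Mut and Hbb-bs at 293 and 513. The difference was uneven over classes. Median log2 ratios were 0.45 for Hba-a1 (range 0.24 to 4.86) and 0.49 for Hba-a2 (-0.58 to 4.15). They were 0.15 for Hbb-bs (-0.17 to 4.09) and 0.025 for Hbb-bt (-0.28 to 3.98). Over all kept cells Six3, a transcription factor of the ventral forebrain, stood at 17.2 CPM in WT and 10.95 in Mut, and Zic1 at 47.4 and 50.01. Immediate early genes in radial glia-like cells had a median log2 ratio of -0.22, with 0.22 in female and -0.31 in male cells.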
